A study of Oncorhynchus kisutch with 221 samples.

How the data were processed

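White muscle of 221 juvenile coho salmon was profiled on 2-colour oligonucleotide arrays, 1 fish per array. Per the labels' protocols, RNA was extracted with a magnetic-bead kit and amplified with an amino-allyl kit. RNA of the fish and a reference pooled from the muscle samples were coupled to different Alexa dyes, the same way round on every array. The table deposited by the authors holds a log ratio, taken here as log2, per probe and array, for 43636 probes named by grid position and 60 control features. The control features were kept out of the comparisons and tested separately.

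The authors' background correction, normalization and rule for blank cells are not given in the sources used here. Of all cells, 47.3% were blank. Array medians lay between -0.0109 and 0.0326, so the deposited log ratios lie centred near 0. The base of the logarithm is not stated. The range of the values exceeds what a common logarithm of scanner signals can reach, and 1 value exceeds the natural logarithm of such a ratio. Base 2 was therefore taken, and every fold rests on it. The orientation of the ratio is not stated either. Probes measured on more arrays of a stage had higher log ratios in that stage: over probes, which are not independent replicates, Spearman's rho was 0.42, 0.26, 0.11, 0.22 and 0.19 in the 5 transitions between consecutive stages. Fish over reference is on this basis the likely orientation, and "higher" means a higher value of that ratio. Arrays correlated with each other down to r = -0.43, and 0.37% of pairs lay under -0.3. The labels state the dyes, and a reference pooled over all stages can give opposite signs in different stages, so the direction was kept.

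The series matrix holds the same values, except for 3168 further blanks on 1 parr array. The highest correlation between 2 arrays was 0.80, and no array was treated as a repeat of another. Titles name every fish a smolt, so fish were grouped by the season label into 6 life stages. The labels number the fish separately. Slide and array position come from the labels' descriptions. Of 60 slides, 37 held more than 1 stage.

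Each probe was fitted with a mean per stage and slide as a random block, in R 4.3.3 with limma 3.58.1. The slide correlation was 0.152, from limma's duplicateCorrelation (statmod 1.5.0) on 3000 probes drawn at random. Because blanks differ between probes, the generalised least squares step was written for the arrays measured at each probe, and it was checked against limma's own fit. Variances were moderated with limma's squeezeVar, and p-values were adjusted by the Benjamini-Hochberg method over the probes tested. A probe was tested if measured on a share of at least 0.5 of the arrays of each group compared. "Called" means an adjusted p under 0.05, and a second count requires at least a 2-fold difference. Folds, log2 differences and SEs come from the fit with the slide term. Means ± SD are of the measured values, so a fold can differ from that of the means beside it. Stages shared 1 estimate of the spread, as did the groups of the other comparisons. The p-values can therefore be too small where a small group spreads more than the others. Origin was compared within smolts, summer and fall fish, and capture area and sex within summer and fall fish, each with the interaction between stages. Permutation tests were 2-sided and used scipy 1.17.1.

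The fit was tested on simulated data with the real blanks, slides and group sizes. Of simulated differences of 1 on the log2 scale, 77.3% were recovered for smolt minus parr, 92.7% for spring minus smolt, 93.8% for summer minus spring, 100% for fall minus summer and 90.3% for winter minus fall. Of simulated differences of 0.5, 22.2%, 48.9%, 54.6%, 92.7% and 26.9% were recovered in the same order. Of the calls, 3.30%, 7.53%, 6.54%, 5.05% and 8.40% were false. The simulation drew each probe independently and gave all stages the same spread. Real arrays share structure over probes, so these rates need not hold for the real data.

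The comparisons, most of the alternatives and the rule for named probes were fixed before the data were examined, other alternatives afterwards, and the filter on blanks once the blanks were seen and before any test. The rule names, per comparison, the 2 called probes with the largest rise and the 2 with the largest fall. No source used here pairs the probes with genes, so the gene lists, named genes and cell type markers planned beforehand were not run. Alternatives changed the slide term, array position, value table, scaling, filters, covariates, fish included and array weights. Under an alternative, directions kept and medians of the log2 difference are of probes called in the reported fit. That fit holds the same fish, so a kept direction is close to given and neither is independent support. The number of arrays limits the precision.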

Results

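The white muscle transcriptome of coho salmon (Oncorhynchus kisutch) was followed from fresh water into the early marine phase. Muscle came from 9 parr, the young river stage, and from 48 smolts, the river stage that is ready for sea water. Fish caught at sea numbered 15 in spring, 64 in summer, 76 in fall and 9 in winter. Fork length averaged 5.09 ± 0.24 cm (SD, n = 9) in parr, 11.3 ± 1.4 cm (SD, n = 48) in smolts and 34.5 ± 2.4 cm (SD, n = 9) in winter fish. Arrays measured between 14061 and 35581 probes, with a median of 22890. Blank cells made up 54.8% ± 4.3 (SD, n = 9) in parr, 46.2% ± 6.5 (SD, n = 48) in smolts and 48.8% ± 14.9 (SD, n = 9) in winter fish. All parr were hatchery fish of the Chilliwack River in 2008 and all spring fish wild fish of 2009, so stage is partly tied to origin, river and year. Other tissues were not analysed here, and gene names of the probes were not used here.

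The first question was whether muscle differed between life stages. Of 18589 probes tested over the 6 stages, 10708 (57.6%) were called by limma's F-test. Stage accounted for 11.1% of the variance over 6659 probes measured on every array, against at most 3.31% in 100 shuffles of the stage labels. Slide accounted for 41.8%, against at most 28.9% in 100 shuffles of the slide labels. The first principal component (17.9% of variance) averaged 32.4 ± 7.6 (SD, n = 9) in parr, 9.02 ± 18.8 (SD, n = 48) in smolts and -13.4 ± 12.5 (SD, n = 76) in fall fish. Winter fish averaged 10.2 ± 26.2 (SD, n = 9). Stage alone accounted for 34.1% of this component and slide alone, with 60 slides, for 56.3%, so a score does not stand for stage alone. Of 12 control features tested over all stages, 5 had an adjusted p under 0.05.

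**Figure D1:**
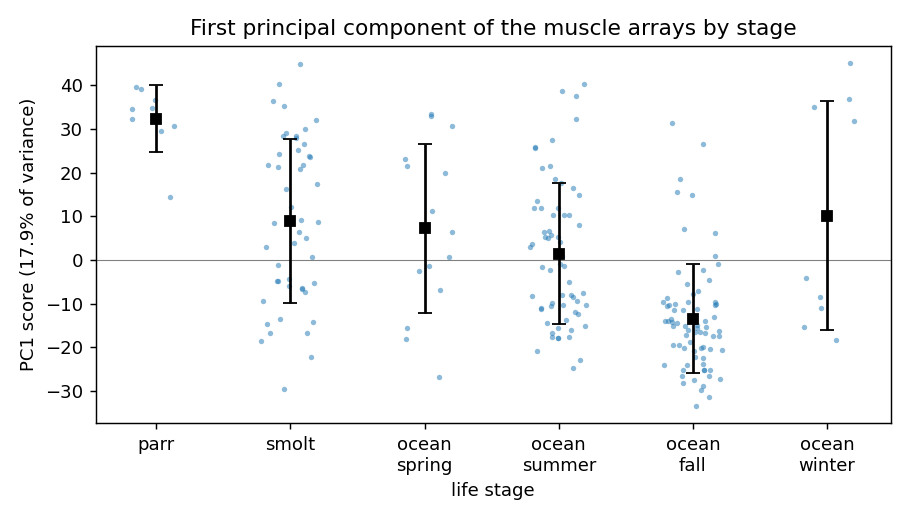
Score of each fish on the first principal component of the log2 ratios (vertical axis, arbitrary units) by life stage (horizontal axis). Points are fish, squares are stage means and bars are 1 SD; parr average 32.4, fall fish -13.4, and the 9 winter fish spread from -18.3 to 45.1.

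Parr and smolts were compared for the river phase. Probe C047R007 was 19.9-fold higher in smolts, at 0.02 ± 1.47 (SD, n = 47) against -4.46 ± 0.44 (SD, n = 9) in parr on the log2 scale. All 47 smolts measured lay above the parr median (log2 difference 4.31, SE 0.55, limma adjusted p = 7.27e-11). Probe C133R131 was 13.8-fold higher, at -1.13 ± 0.94 (SD, n = 48) against -5.01 ± 1.82 (SD, n = 9) in parr. On it 48 of 48 smolts lay above the parr median (log2 difference 3.78, SE 0.38, limma adjusted p = 3.79e-16). Probe C249R116 was 20.7-fold lower in smolts, at -2.10 ± 2.52 (SD, n = 48) against 2.51 ± 1.54 (SD, n = 9) in parr (limma adjusted p = 1.51e-05). Probe C151R127 was 15.6-fold lower (log2 difference -3.96, SE 0.85, limma adjusted p = 0.000176). Of 19097 probes tested, 3408 were called, 1568 higher and 1840 lower in smolts, and 576 differed by at least 2-fold, 379 of them higher. Parr fish 9, the only parr that shared a slide with a smolt, lay apart from the other 8 parr on C133R131, C249R116 and C151R127, and 4020 probes were called without it, with log2 differences of 4.52, -5.09 and -4.54 on these 3 probes against 3.78, -4.37 and -3.96 with it. Spring fish 2 had values near those of the other 8 parr on all 4 probes, at -4.63, -6.18, 2.48 and 1.98 in the order named. The calls made up 17.8% of the probes tested, and 7.98% after quantile normalization. With slide as a fixed effect they made up 1.78%, of which 65% were higher in smolts against 46.0% as reported, and the calls of C249R116 and C151R127 ended at log2 differences of -3.28 and -3.34. The 576 probes of at least 2-fold then had a median of 0.864 of their log2 difference, and 0.739 after quantile normalization. With slide fixed, the 4 parr on a slide of parr alone added nothing to this comparison. The only slide with both parr and smolts was that of parr fish 9. The lower share called can therefore not be read as the part of the difference due to slide. The calls of C249R116 and C151R127 also ended against Chilliwack smolts alone, at log2 differences of -2.32 and -1.76.

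**Figure D2:**
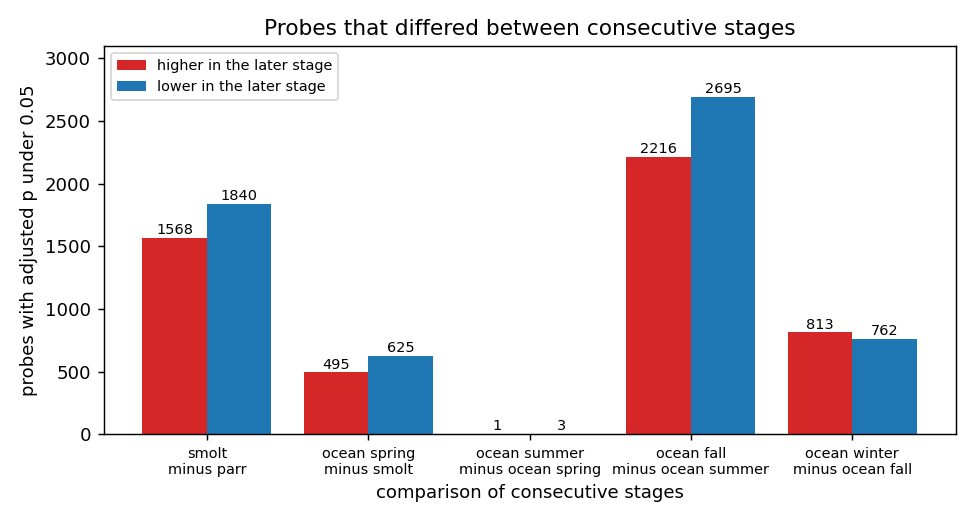
Number of probes with an adjusted p under 0.05 (vertical axis) in each comparison of consecutive stages (horizontal axis), as bars for probes higher and lower in the later stage. Fall minus summer has 2216 higher and 2695 lower, and summer minus spring 1 higher and 3 lower.

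Smolts and wild fish caught at sea in spring were compared for the entry into sea water. Probe C151R100 was 8.82-fold higher at sea, at -0.17 ± 2.11 (SD, n = 15) against -2.93 ± 2.47 (SD, n = 48) in smolts, and 13 of 15 spring fish lay above the smolt median (limma adjusted p = 0.00605). Probe C168R092 was 6.86-fold higher, with 15 of 15 spring fish above the smolt median (log2 difference 2.78, SE 0.68, limma adjusted p = 0.00801). Probe C227R074 was 3.02-fold lower at sea (log2 difference -1.59, SE 0.33, limma adjusted p = 0.00214). Probe C231R139 was also 3.02-fold lower, at -1.88 ± 0.71 (SD, n = 15) against -0.37 ± 1.33 (SD, n = 48) in smolts (limma adjusted p = 0.00565). Of 21370 probes tested, 1120 were called, 495 higher and 625 lower at sea, and 43 differed by at least 2-fold. No slide held both stages, and 6 of 18 control features tested were called too, with log2 differences of up to 0.27 in size. Without spring fish 2, 1247 were called. The calls made up 5.24% of the probes tested. This share was 7.91% in wild fish, 0.970% with slide as a fixed effect, 1.48% after quantile normalization and 1.83% with origin and year as covariates, where the 43 probes of at least 2-fold had medians of 1.05, 1.41, 0.943 and 0.942 of their log2 difference in the same order. Against wild smolts of 2009 alone they made up 0.290%, which ended the calls of all 4 probes. The probes of at least 2-fold then had a median of 0.773 of their log2 difference. All 1118 called probes tested kept their direction, which was close to given, as they were called with the same fish.

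Few probes were called between spring and summer at sea. Probe C066R052 was 1.90-fold higher in summer, at -0.12 ± 0.59 (SD, n = 60) against -1.03 ± 0.40 (SD, n = 9 of the 15 spring fish), with a limma adjusted p of 0.0343. Probe C225R060 was 1.53-fold lower in summer, at 0.10 ± 0.41 (SD, n = 62) against 0.69 ± 0.50 (SD, n = 15). Probe C164R148 was 1.31-fold lower, and both had a limma adjusted p of 0.0343. Of 21173 probes tested, 4 were called by limma, 1 higher and 3 lower, and 2149 had an unadjusted p under 0.05. The noise-corrected root mean square log2 difference over probes was 0.13 (jackknife SE 0.05), against 0.20 (SE 0.04) for spring minus smolt. The count lay between 0 and 15 over 17 alternative settings, and the calls of all 3 probes ended after quantile normalization, with log2 differences of 0.74, -0.57 and -0.33 against 0.93, -0.61 and -0.39 as reported.

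Between summer and fall at sea, many probes moved by small amounts. Probe C226R055 was 3.47-fold higher in fall, at -0.05 ± 1.77 (SD, n = 76) against -1.78 ± 1.21 (SD, n = 63) in summer (limma adjusted p = 6.08e-07). Probe C092R164 was 2.31-fold higher (log2 difference 1.21, SE 0.28, limma adjusted p = 0.000699), and its call ended in hatchery fish alone, at a log2 difference of 0.51. Probe C057R042 was 2.47-fold lower in fall, at -2.06 ± 0.97 (SD, n = 76) against -0.72 ± 0.94 (SD, n = 64), and 66 of 76 fall fish lay below the summer median (limma adjusted p = 5.72e-08). Probe C151R127, also lower in smolts than in parr, was 2.26-fold lower in fall (limma adjusted p = 0.0149), and this call ended in 5 of 17 alternative settings: with slide as a fixed effect (log2 difference -0.79), after quantile normalization (-0.89), in fish of 2009, in wild fish and without west coast fish. Of 21797 probes tested, 4911 (22.5%) were called, 2216 higher and 2695 lower, and 26 differed by at least 2-fold. The noise-corrected root mean square log2 difference was 0.18 (jackknife SE 0.02), against 0.39 (SE 0.06) for smolt minus parr. The share called was 9.52% with slide as a fixed effect, 12.5% in fish of 2009, 6.45% in wild fish and 14.1% in hatchery fish, where the 26 probes of at least 2-fold had medians of 0.925, 0.941, 1.00 and 1.15 of their log2 difference in the same order. Of 18 control features, 1 was called.

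Between fall and winter at sea, probe C119R085 was 4.04-fold higher in winter, at 0.08 ± 2.10 (SD, n = 9) against -1.81 ± 1.41 (SD, n = 76) in fall, and 8 of 9 winter fish lay above the fall median (limma adjusted p = 0.00909). Probe C056R089 was 3.96-fold higher (log2 difference 1.99, SE 0.48, limma adjusted p = 0.00599). Probe C248R119 was 3.70-fold lower in winter, at -2.04 ± 2.05 (SD, n = 9) against -0.23 ± 1.33 (SD, n = 76), with 7 of 9 winter fish below the fall median (limma adjusted p = 0.0111). Probe C155R124 was 3.30-fold lower (limma adjusted p = 0.0172). On all 4 probes winter fish spread more than fall fish, with SDs of at least 1.94 against at most 1.41. Since the stages shared 1 estimate of the spread, the p-values and calls of this comparison may be too strong. Of 21211 probes tested, 1575 (7.43%) were called, 813 higher and 762 lower, and 167 differed by at least 2-fold. Winter fish 4, 6 and 8 shared a slide and had 66.0%, 67.8% and 67.1% of cells blank, and 2462 probes were called without that slide. The share called was 0.941% with slide as a fixed effect, 2.50% in wild fish and 0.635% without west coast fish, where the probes of at least 2-fold had medians of 1.04, 1.24 and 1.10 of their log2 difference. Over 19 alternative settings the calls of C119R085, C248R119 and C155R124 ended in 5 each and that of C056R089 in 4. In hatchery fish 3 probes were called and among west coast fish 1, and the calls of all 4 probes ended in both. The probes of at least 2-fold, chosen partly from the same fish, had a median of 0.789 and 0.925 of their log2 difference.

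**Figure D3:**
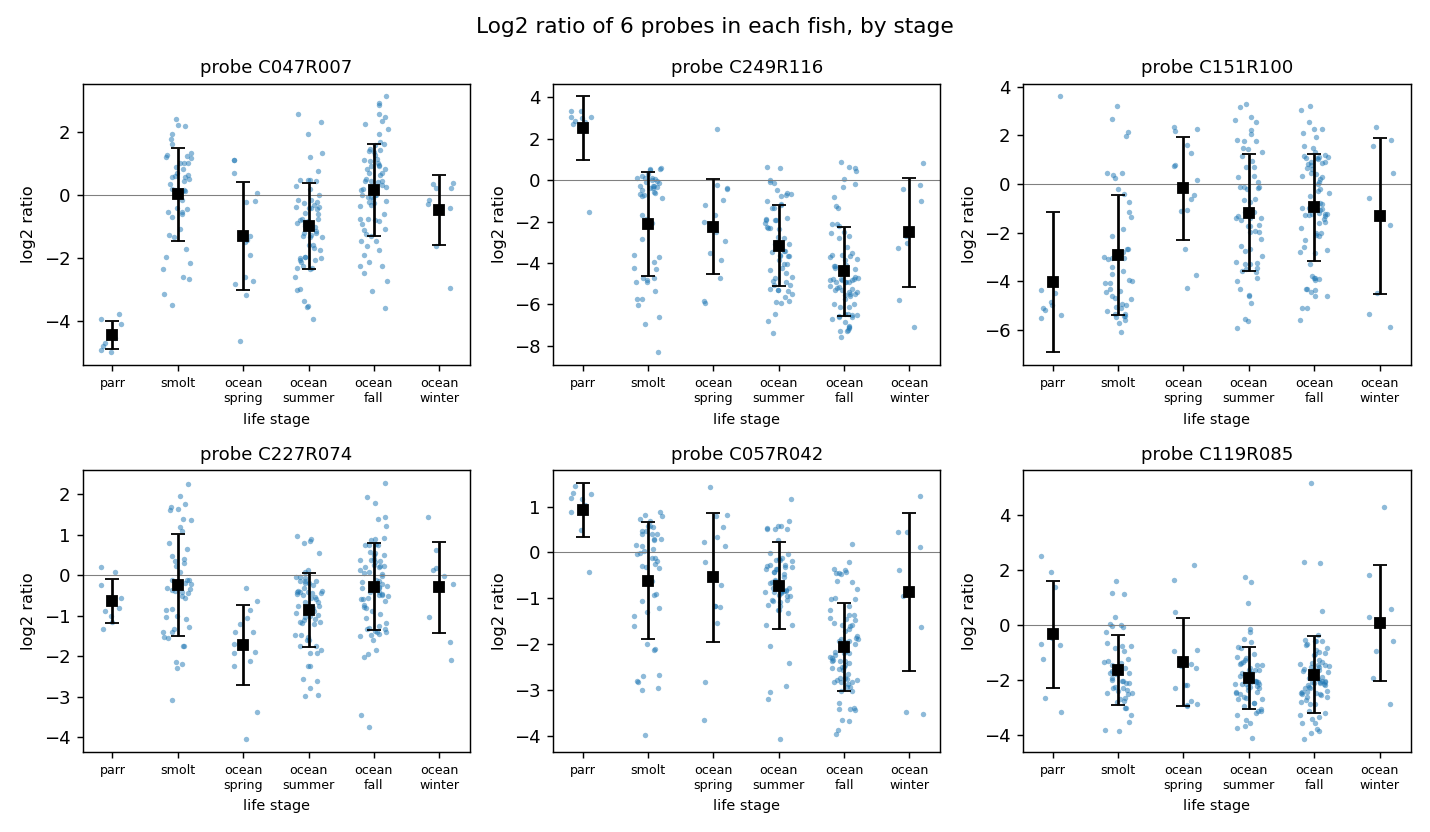
Log2 ratio of 6 probes (vertical axes) in each fish, by life stage (horizontal axes). Points are fish, squares are stage means and bars are 1 SD; C047R007 averages -4.46 and C249R116 2.51 in parr, and C057R042 averages -2.06 in fall.

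Hatchery and wild fish were compared within stages. In smolts, probe C151R108 was 3.64-fold higher in hatchery fish, at 0.09 ± 0.98 (SD, n = 28) against -1.97 ± 1.68 (SD, n = 20) in wild fish, and 28 of 28 hatchery smolts lay above the wild median (limma adjusted p = 9.60e-06). Wild smolts of the Salmon River averaged -0.16 ± 1.40 (SD, n = 6), level with hatchery smolts of the Capilano (-0.17 ± 1.24, SD, n = 9) and Puntledge (-0.25 ± 0.95, SD, n = 9), while wild Chilliwack smolts averaged -3.13 ± 0.79 (SD, n = 8) and wild Capilano smolts -2.22 ± 1.32 (SD, n = 6). Probe C109R126 was also 3.64-fold higher (limma adjusted p = 0.00547). It averaged 2.09 ± 3.03 (SD, n = 10) in Chehalis smolts, but -1.83 ± 0.92 (SD, n = 9) and -1.95 ± 0.87 (SD, n = 9) in Capilano and Puntledge hatchery smolts, and its call ended in 4 of 13 alternative settings, with capture site as a covariate at a log2 difference of 0.62. Probe C104R036 was 7.78-fold lower in hatchery smolts, at -3.38 ± 1.06 (SD, n = 28) against -0.28 ± 3.31 (SD, n = 20) in wild smolts (limma adjusted p = 0.000251). Probe C010R062 was 3.86-fold lower (limma adjusted p = 0.000435). Of 22285 probes tested in smolts, 1379 (6.19%) were called, 581 higher and 798 lower in hatchery fish. With slide as a fixed effect this balance turned, to 693 higher and 483 lower. More stayed lower than higher in fish of 2009 (165 and 84) and with fork length as a covariate (370 and 232). Limma called 0 probes in summer (26 hatchery, 38 wild) and 0 in fall (30 hatchery, 46 wild), where 1079 and 2177 probes had an unadjusted p under 0.05. The difference between origins itself differed from that in smolts at 511 probes in summer and 179 in fall (73 and 13 in fish of 2009, 65 and 58 with Capilano smolts alone, 73 and 58 with capture site as a covariate), and at 0 between fall and summer by limma, where 2218 had an unadjusted p under 0.05. In smolts the share called was 1.12% in fish of 2009, 0.626% within the Capilano River and 0.736% with capture site as a covariate, where the probes of at least 2-fold had medians of 0.857, 0.883 and 0.891 of their log2 difference. With fork length as a covariate it was 2.70%, and the probes of at least 2-fold had a median of 0.932 of their log2 difference. All 1379 called probes kept their direction, which was close to given, as they were called in the same fish. Hatchery smolts measured 12.0 ± 1.0 cm (SD, n = 28) and wild smolts 10.25 ± 1.20 cm (SD, n = 20).

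Fish from the west coast of Vancouver Island were compared with fish from the Strait of Georgia. Capture area was tied to the stock region given in the labels. All west coast summer fish were of Columbia, Oregon or North stock, and no strait summer fish was labelled so. Most west coast fall fish were of Columbia, Oregon, Puget Sound or North stock, which was rare in the strait. Area and stock can therefore not be told apart in these comparisons. In fall, probe C092R164 was 3.70-fold higher on the west coast, at 1.77 ± 0.95 (SD, n = 10) against -0.05 ± 1.38 (SD, n = 66), and 10 of 10 west coast fish lay above the median of the strait (limma adjusted p = 0.0386). Probe C226R135 was 2.61-fold higher (limma adjusted p = 0.0292). Probe C124R072 was 4.99-fold lower on the west coast, at -3.10 ± 3.14 (SD, n = 10) against -1.11 ± 1.54 (SD, n = 66), with a limma adjusted p of 0.0386. Its p-value may be too small, as the west coast fish spread more. Probe C044R036 was 2.89-fold lower, at -1.87 ± 0.60 (SD, n = 10) against -0.55 ± 1.21 (SD, n = 66), with a limma adjusted p of 0.0412. Of 21726 probes tested in fall, 168 were called, 109 higher and 59 lower on the west coast. In summer 1 of 21645 was called, C114R061, which was 2.82-fold higher in the west coast fish, at 0.68 ± 0.96 (SD, n = 8) against -0.73 ± 0.78 (SD, n = 56), with a limma adjusted p of 0.0383. The difference between areas itself differed between the seasons at 14 probes. This count ranged from 3, with slide as a fixed effect, to 75, without a slide term, over 11 alternative settings. West coast fall fish were longer, 30.1 ± 2.9 cm (SD, n = 10) against 24.6 ± 2.3 cm (SD, n = 66), and with fork length as a covariate 20 probes were called in fall and, by limma, 0 in summer (1147 at an unadjusted p under 0.05), none of these 5 probes among them. The 31 fall probes of at least 2-fold then had a median of 0.850 of their log2 difference, and the summer probe 0.965 of it, but C092R164 fell from a log2 difference of 1.89 to 0.85. Over 11 alternative settings the calls ended in 4 for C124R072, 3 for C226R135 and 2 each for C092R164, C044R036 and C114R061.

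Males and females differed in fall at 2 of 21850 probes. Probe C098R070 was 3.59-fold higher in males, at 0.78 ± 1.57 (SD, n = 35) against -1.12 ± 1.24 (SD, n = 34) in females (limma adjusted p = 0.00103). Probe C108R116 was 3.19-fold higher in males, and 33 of 37 males lay above the female median (log2 difference 1.68, SE 0.32, limma adjusted p = 0.00588). With slide as a fixed effect limma called 0 probes, and 892 had an unadjusted p under 0.05. Both probes, chosen in the same fish, kept their direction, with a median of 0.953 of their log2 difference. The call of C108R116 ended in 3 of 11 alternative settings, at log2 differences of 1.57 or more. In summer (33 males, 20 females) limma called 0 of 21678 probes, and 1019 had an unadjusted p under 0.05. The difference between the sexes was called as differing between summer and fall at 0 of 21319 probes by limma, and 655 had an unadjusted p under 0.05.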

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

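The tests of a label exchange and of the slide that held parr alone, the fits without parr fish 9, without spring fish 2 and without the slide of 3 winter fish, and the placement of parr fish 9 were chosen after the results were seen. Tests that replaced earlier ones were fixed before their own results but after those of the earlier ones. An earlier test of slide for parr, the share of probes called again with slide as a fixed effect, gave 32.6% of 576 and decided nothing. Earlier tests of capture area for winter gave 0 of 156 probes called again among west coast fish, which would have counted for area, and then a median of 0.906 of the size of the differences, on probes chosen partly from the same fish. An earlier test of capture area between spring and summer, 5 probes called with the southern Strait of Georgia alone, was replaced because it used 20 of the 64 summer fish, so that its count is not comparable with the reported one.

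Parr fish 9 stood far from the other parr on 3 probes, at -0.65 on C133R131, -1.54 on C249R116 and -1.12 on C151R127. The array median of winter fish 1, 0.0255, stood far from those of the other winter fish. In all, 4 of 20 sets of values tested held such a fish, where chance gives about 1 in 20 for independent sets. These sets were not independent: 3 of the 4 were parr fish 9 on probes picked for the same comparison. The count can thus not be weighed against chance. The difference between hatchery and wild fish in smolts was not that of summer fish at 511 probes, nor that of fall fish at 179, but with Capilano smolts alone these counts were 65 and 58. The difference between west coast and strait fish in fall was not that of summer at 14 probes, but with slide as a fixed effect this count was 3.

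Parr differed from smolts, but with the smolt mean at 0 and the mean of the other 8 parr at 1, over 781 probes chosen without them, parr fish 9 lay at 0.156 and spring fish 2 at 0.922, the other 8 parr lying between 0.879 and 1.11 and the other 14 spring fish between -0.277 and 0.234. The tables argue against river and year alone as the whole cause, since 445 of 576 probes were called again in the same direction against Chilliwack smolts of 2008 alone. They argue against origin alone, since 543 of 575 were called again among hatchery fish. No smolt matched the parr in river, year and origin at once: the Chilliwack smolts were wild, and the hatchery smolts came from other rivers in 2009. River, year and origin together are therefore not excluded. They argue against slide for the 4 parr on slides with other stages, since the 4 fish of other stages there had a median shift of -0.108 of the parr shift, the highest being 0.0549, while for the 4 parr on a slide of parr alone slide and stage cannot be told apart, as 0 fish of other stages lay on it. An exchange of the labels of parr fish 9 and spring fish 2 may explain both fish: on 1017 probes that separate the other parr (1) from the other spring fish (0), parr fish 9 lay at 0.255, near the highest of the other spring fish (0.259), and spring fish 2 at 0.936, within the other parr (0.887 to 1.11). Not every probe goes with an exchange. On C047R007 parr fish 9 lay with the other parr, all parr averaging -4.46 ± 0.44 (SD, n = 9), against -1.31 ± 1.71 (SD, n = 15) in all spring fish. Smolts and summer, fall and winter fish cannot be ruled out as the source of parr fish 9. On the 781 probes its 0.156 lay within the range of each of these stages, so its place is not particular to spring fish. A difference among fish of a stage is untested, and the stage itself stays open for the other parr.

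Winter fish differed from fall fish, unevenly: fish 1, 2, 5 and 7 scored from 32.0 to 45.1 on the first principal component and fish 3, 4, 6, 8 and 9 from -18.3 to -4.17, where fall fish averaged -13.4. The slides of fish 1, 2, 5 and 7 were not left out in turn, so slide stays open for these fish. The tables argue only against the single slide of winter fish 4, 6 and 8, since 165 of 167 probes of at least 2-fold difference were called again in the same direction without it, and those 3 fish are among the 5 that scored like fall fish. They argue against capture area as the whole cause, since the winter minus fall difference of the 3 strait winter fish correlated with that of the 6 west coast winter fish over 21211 probes with Spearman's rho = 0.55, against -0.37 to 0.44 in 99 draws of 3 strait fall fish. Without the west coast fish that shared a slide with a strait fish rho was 0.38, and again 1 of 100 was as high, the observed one included. The season itself stays open and untested, as does what sets the 4 winter fish apart. Origin partly goes with this split: fish 1, 2 and 5 were wild and fish 7 hatchery, while fish 3, 4, 6 and 8 were hatchery and fish 9 wild. It was not tested as a cause of the split.

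Few probes differed between spring and summer. Too few fish cannot be told apart from a small difference: in 20 draws of 15 fall fish against the summer fish the median count was 536.5 and 16 draws called over 100, a median over 100 having been set beforehand as counting against it, but draws ranged from 1 to 2886, so the bound was not passed beyond their spread, and the same test called 0 probes between summer and spring. Changes that differ between capture areas may hide a larger difference: all 15 spring fish came from the southern Strait of Georgia, and the noise-corrected root mean square log2 difference from them was 0.19 for the 20 southern summer fish, against a median of 0.13 for sets of 20 summer fish of all areas. Of 100 sets, the southern one included, 3 were as high. The slides of the southern fish were not tested as a source of this.

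Fish were regrouped at random within the comparison, 100 splits each with the real one included, in a fit of the compared fish without a slide term. Chance can be excluded for the stages together, where 1 split reached the real count of 11990 and the highest other called 13. It can be excluded, with 1 split each, for smolt minus parr (4918, highest other 2), spring minus smolt (1892 and 1), fall minus summer (5692 and 1) and winter minus fall (2401 and 41). For origin in smolts 1 split reached the real count too (2226 and 673), which excludes chance over single fish but not over rivers. The same holds for the change of the origin difference from smolts to summer (823 and 7) and to fall (759 and 9). For the change of the area difference from summer to fall 1 split reached the real count (75, highest other 57). For area in fall 2 splits did (279 and 926) and for sex in fall 4 splits (2 and 105). With no correction over the comparisons tested, and random splits near or above the real counts, chance is not excluded for these. Splits with 926 and 105 calls, several times the real counts, point to a structure of the samples, the cause of which was not tested; slide is not excluded, since this fit had no slide term. For origin in fall against summer this fit called 3 probes, which 2 splits reached (highest other 3), but the reported count was 0 and there is no call to test. Where this fit called 0, all 100 of 100 splits reach that by construction and the splits say nothing on chance: summer minus spring (highest other 9; 4 calls as reported), area in summer (2; 1 call as reported), origin in summer (29) and fall (9), sex in summer (1) and the change of the sex difference (2). Regrouping parts fish of a slide, so slide effects are not covered. It also parts smolts of a river, and only the Capilano held smolts of both origins, so river effects are not covered either.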

How the results depend on the processing

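The filters of at least 3 values and of 90% measured arrays, and the fits without the slide of 3 winter fish, without parr fish 9 and without spring fish 2, were chosen after seeing the data. Of the counts under alternatives, 74 did not stay within 1.5 times the reported count, and all others did. No named probe changed direction under the alternatives run, but a change was unlikely for the largest called differences of the same fish. The call of a named probe held in 382 cases and ended in 74. Some alternatives, such as the series matrix, hardly changed the values, so these counts do not measure robustness. Limma's counts of 0 for origin in summer, for sex in summer and for the change of the sex difference were 0 under the 13, 11 and 11 alternatives run, with 1079, 1019 and 655 probes at an unadjusted p under 0.05 as reported. The gene list alternatives were not run, for want of gene names. No paired analysis was possible because the numbers of the fish only follow the order of the record. Subsets compare fewer fish, and the stages together in subsets cover fewer stages; otherwise the cause was not tested. What signal over background limits is unknown, since only ratios were used.

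Comparisons with more than 100 calls as reported are given as percent of probes tested and the others as counts; within 1.5 times was judged on counts throughout. The reported shares were 17.8% for smolt minus parr, 5.24% for spring minus smolt, 22.5% for fall minus summer, 7.43% for winter minus fall, 57.6% for the stages together, 6.19% for origin in smolts, 2.39% and 0.839% for origin in summer and in fall against smolt and 0.773% for area in fall. Without a slide term, the shares were 9.32% for spring minus smolt, 10.4% for origin in smolts, and 4.54% and 2.80% for origin in summer and in fall against smolt. The counts were 15 for summer minus spring, 11 for origin in fall, 2 for origin in fall against summer, 6 for area in summer and 75 for the change of the area difference. With slide as a fixed effect, the shares were 1.78% for smolt minus parr, 0.970% for spring minus smolt, 9.52% for fall minus summer, 0.941% for winter minus fall and 3.97% for origin in summer against smolt. The counts were 1 for summer minus spring, 4 for origin in fall, 10 for area in summer, 3 for the change of the area difference and 0 for sex in fall (limma, 892 at an unadjusted p under 0.05). Among origin calls in smolts, 58.9% were then higher in hatchery fish, against 42.1% as reported. Slides holding both stages numbered 1 for smolt minus parr, 0 for spring minus smolt and 2 for winter minus fall.

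After quantile normalization, the shares were 7.98% for smolt minus parr, 1.48% for spring minus smolt, 1.56% for origin in summer against smolt and 1.31% for area in fall. The counts were 0 for summer minus spring (limma, 1417 at an unadjusted p under 0.05), 4 for area in summer, 22 for the change of the area difference and 1 for sex in fall. Without the least variable probes, summer minus spring gave 0 and origin in fall 1. Array position as a covariate gave 4 for area in summer. Array weights gave 32.5% for smolt minus parr and 3.86% for winter minus fall. The filter of 90% gave 1 for origin in fall and 1 for sex in fall.

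With origin and year as covariates, spring minus smolt gave 1.83% and summer minus spring 2 probes. Fish of 2009 gave 2.05% for spring minus smolt, 12.5% for fall minus summer, 33.4% for the stages together, 1.12% for origin in smolts, and 0.340% and 0.0611% for origin in summer and in fall against smolt. They gave 3 probes for area in summer, 8 for the change of the area difference and 1 for sex in fall. Wild fish gave 7.91% for spring minus smolt, 0 probes for summer minus spring, 6.45% for fall minus summer, 2.50% for winter minus fall and 34.2% for the stages together. Hatchery fish gave 14.1% for fall minus summer, 0.0182% for winter minus fall and 37.3% for the stages together. Without west coast fish, summer minus spring gave 7 probes and winter minus fall 0.635%. With only the stages compared in the fit, spring minus smolt gave 2.38% and summer minus spring 0 probes. Against wild smolts of 2009, spring minus smolt gave 0.290%. Winter minus fall gave 0.00493% among west coast fish and 11.1% without the slide of 3 winter fish.

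With fork length as a covariate, the shares were 2.70% for origin in smolts, 0.952% for origin in summer against smolt and 0.0921% for area in fall, and the counts 1 for origin in fall, 0 for area in summer and 6 for the change of the area difference. With capture site as a covariate, they were 0.736% for origin in smolts, 3 probes for origin in fall, and 0.341% and 0.272% for origin in summer and in fall against smolt. With Capilano smolts alone, they were 0.626%, 8 probes, 0.303% and 0.272% in the same order.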

Other observations

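The tests of the sexes outside fall, of rivers and years and of single winter fish were chosen after the main results were seen; the tests of both hypotheses were fixed before their results were seen.

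The mean of the winter fish lay close to that of the smolts, but single winter fish did not lie at the smolt mean on the first principal component (9.02): 4 scored from 32.0 to 45.1 and 5 from -18.3 to -4.17. The noise-corrected root mean square log2 difference over 18589 probes was 0.12 between the means of winter fish and smolts and 0.27 between those of fall fish and smolts. Limma called 3 of 21506 probes between winter fish and smolts and 7200 of 22063 between fall fish and smolts, with 9 winter and 76 fall fish. From parr, the same distance was 0.39 for smolts, 0.40 for spring, 0.46 for summer, 0.57 for fall and 0.38 for winter fish.

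Some probes split smolts within a river. On C104R036, wild Capilano smolts ranged from -4.60 to 4.94 (n = 6) and wild Chilliwack smolts from -3.90 to 4.54 (n = 8), while hatchery smolts of the Capilano ranged from -4.42 to -2.89 (n = 9). On C109R126, Chehalis smolts ranged from -2.59 to 4.75 (n = 10). Between wild Salmon River and Capilano smolts (6 each) limma called 3 probes. It called 0 between each pair of hatchery rivers, with 2083, 1632 and 1466 probes at an unadjusted p under 0.05. Between 2009 and 2008, limma called 337 probes in fall (68 and 8 fish) and 3 in summer (57 and 7 fish). All fall fish of 2008 were wild fish of the strait, while all hatchery and west coast fall fish were of 2009. Year is thus mixed with origin and area in fall. Measured cells differed too: 809 probes were measured on a higher share of smolt than parr arrays and 8 on a lower share (Fisher's exact test, adjusted).

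The probes that differed between the sexes in fall were tested in other stages, 6 tests in all. In summer, C108R116 was higher in males by 1.26 on the log2 scale (n = 33 and 20), with a permutation p of 0.00464 (adjusted 0.0278). C098R070 was higher in males by 0.90 (n = 28 and 20), with a permutation p of 0.0233, and this did not pass the correction (adjusted 0.0700). In smolts the male minus female differences were -1.07 and -0.50 (n = 9 and 6, exact permutation p = 0.249 and 0.393). In winter they were 1.01 and 0.49 (exact permutation p = 0.365 and 0.571).

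A hypothesis is that the change from fall to winter may be in part a return of the change from summer to fall. With the fall fish divided by slide so that each difference used other fall fish, winter minus fall and fall minus summer correlated over 21012 probes with a median Spearman's rho of -0.50 in 21 divisions (-0.58 to -0.40). With 9 fall fish in place of the winter fish, 99 draws gave rho from -0.47 to 0.47, so 1 of 100 was as low, the observed one included. Taken singly, winter fish 1, 2, 5 and 7 gave rho of -0.51, -0.45, -0.60 and -0.55, and the other 5 winter fish from -0.04 to 0.20, where the 76 fall fish taken singly gave -0.57 to 0.41 with a median of 0.06. The correlation is thus carried by 4 of the 9 winter fish, though without any 1 winter fish rho lay between -0.56 and -0.44, with at most 2 of 100 as low. The test came out as the hypothesis predicts for the mean of the winter fish, not for each of them, and it does not separate season from handling that the labels leave out.

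A second hypothesis was that the change from summer to fall could follow body size. Slopes on fork length within summer fish correlated over 21797 probes with the fall minus summer difference, with Spearman's rho = 0.56 and a permutation p of 0.01, the smallest that 99 permutations can give. Within fall fish rho was 0.33 (permutation p = 0.17). A p under 0.05 in both stages had been required, so the question stays open.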
